A study of Xenopus tropicalis with 3 samples.

How the data were processed

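Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open DNA, in the urostyle of Xenopus tropicalis tadpoles at stages 56, 61 and 65, with 1 library per stage. Per the labels' protocols, tissue was dissected on ice, crushed with a pestle and taken through the Omni-ATAC procedure. The series' design text speaks instead of laser capture, so how the tissue of each library was isolated is not settled by the labels. With no replicate at any stage, no test between stages was made and no p-value is given for any difference between stages.

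The deposited data are 3 peak lists, 1 per library, with no pooling of libraries as far as the labels say. Bowtie2, Picard, MACS2 and Genrich are named in the submitters' processing notes, without versions or roles. Genome build, read filters, peak-calling settings and any shift of reads for the transposase offset are not given in the sources used here. The lists were not made alike. In the deposited lists of stages 56 and 61, the signal column held a peak area with a smallest value just above 20, and the deposited score equalled 1000 times that area divided by the peak width, capped at 1000, within 1 unit in 100% of peaks. An area grows with peak width and with sequencing depth, so it was used to rank and describe peaks within a list. In the deposited stage 65 list the same column held a fold (a ratio of summit pileup to background), and the deposited score was 10 times the −log10 q, not capped, within 1 unit in 100% of peaks. All 3 deposited lists gave −log10 p and −log10 q at the summit, and the smallest −log10 q was 1.45, 1.44 and 1.45 at stages 56, 61 and 65. Areas and folds were never compared with each other.

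The total read count of each library is not given in the sources used here. At stage 65 some depth could be recovered, because the deposited folds were whole multiples of 0.150 in 100% of peaks, within 0.01 of a whole number for multiples of ordinary size and within the rounding of the file for the largest. With a pseudocount of 1 in the fold, this step gives 1 genome-wide background pileup of 5.68 fragments. The deposited −log10 p followed a Poisson tail with that mean, with a median absolute difference of 2.4e-06 over 303613 peaks. The median summit pileup was 21 fragments (interquartile range 17 to 27, minimum 12). No such steps exist in the area column, so the depth behind stages 56 and 61 is unknown.

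Chromosome names differed between the lists. Stages 56 and 61 used names of the xenTro9 kind (chromosomes 1 to 10 and many unplaced scaffolds), while stage 65 used plain chromosome numbers and contig accessions. The gene table used here was of UCB_Xtro_10.0. On every chromosome from 1 to 10 the last stage 65 peak ended just beyond the last protein-coding gene of that table, for example at 217471066 on chromosome 1, whereas the last peak of stages 56 and 61 ended at 194771579. Summits of stage 65 peaks were 1.24 times as frequent within 500 bp of protein-coding gene ends as 5 to 10 kb away. The ratio was 0.783 at stage 56 and 0.883 at stage 61, but only 0.103% and 0.216% of gene ends had a summit there. These ratios are too loose to tell builds apart. Stage 65 was therefore annotated with the table, stages 56 and 61 were compared by position with each other, and no coordinate was converted between builds. Coordinates are 1-based.

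Several planned steps could not be carried out as designed. The gene table holds no strand, so peaks were assigned to both ends of a gene, within 1 kb to each side, and a gene end stands for a start or a finish without distinction. Stages 56 and 61 received no gene annotation and no overlap with stage 65. The planned search for transcription factor motifs was not run, because no genome sequence was used here, and promoter GC content was not matched for the same reason.

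Peaks of stages 56 and 61 overlapped when they shared at least 1 bp. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Each share is set beside the mean of 100 seeded placements of the same peaks at random on the same chromosome or scaffold, up to the last peak end seen there. The share of occupied genes, and the gene-end share under other settings, rest on 20 placements. A placed peak is one on chromosomes 1 to 10. A placed peak is called isolated when no other peak of its list lay within 50 kb, and clustered when one lay within 10 kb.

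The 21 gene lists were fixed before the data were examined, as were the overlap rule, the window of 1 kb, the ranking column, the rules for naming genes and the other settings tried, except 3 that the closing section names. Of 296 list members, 268 matched a protein-coding symbol of the table. For each list the number of members with a peak at a gene end was placed among 10000 seeded random lists of the same size matched on deciles of gene length, with ties split evenly, and the same was done for the median fold of the best gene-end peak, with genes lacking one set to 0, and for the number of peaks per 10 kb of gene and flanks. A percentile describes this library and is not a p-value. Of each list, up to 4 members are named, in the order of the rank of their best gene-end peak, and a few members are not reported here. List members without a gene-end peak are named as well, and these were chosen after their values were seen. The 5 protein-coding genes with a symbol and the highest-ranking gene-end peaks at stage 65 are named, as are the 3 highest peaks of each stage. A further rule, on genes present in some stages only, could not be applied across builds. Other features are named as chosen after their values were seen.

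Alternatives used the stronger 50% of each list, equal numbers of peaks, merging of peaks within 100 bp, placed chromosomes, windows of 500 bp and 2.5 kb, gene bodies with 10 kb flanks and stricter overlap. Overlap and list routines were tested on simulated data: all 1800 planted overlaps among 3000 peaks were found and 0 touching pairs were called. Of 200 random lists drawn from 20000 simulated genes, 97.5% lay between percentiles 2.5 and 97.5, and 100% of lists with 14 of 15 members occupied lay above the latter, with simulated genes less often occupied than the real ones. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.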

Results

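The urostyle is the rod-shaped bone at the rear of the frog trunk, which forms during metamorphosis while the tail is lost. Accessible chromatin in this tissue was profiled at stage 56, stage 61 and stage 65 of Xenopus tropicalis, with 1 library per stage. The peak lists held 4564 peaks at stage 56, 6806 at stage 61 and 311625 at stage 65. They covered 2.55, 3.56 and 290.9 Mb, with median peak widths of 380, 383 and 569 bp. Since there were no replicates, differences between stages were not tested against biological spread, and all intervals cover counting error only. Stages 56 and 61 shared one coordinate system and one kind of list, whereas stage 65 differed in both, so the first pair was compared by position and stage 65 was described against gene annotation.

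The first comparison asked which accessible sites differed between stage 56 and stage 61. The excess at stage 61 was larger among peaks that stood alone on chromosomes than among crowded ones. Isolated peaks, with no other within 50 kb, numbered 506 at stage 56 and 1286 at stage 61, a ratio of 2.54, whereas clustered peaks, with another within 10 kb, numbered 1150 and 1512, a ratio of 1.31. Every one of chromosomes 1 to 10 carried more peaks at stage 61. Chromosome 2 had the highest ratio, with 177 peaks at stage 56 and 428 at stage 61 (2.42), followed by chromosome 3 with 137 and 311 (2.27). Chromosome 6 had the lowest, with 308 and 439 (1.43). On unplaced scaffolds the ratio was 1.26, and across the whole list it was 1.49.

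Unplaced scaffolds carried a large part of both lists. They held 59.8% of stage 56 peaks (58.3 to 61.2) and 50.4% of stage 61 peaks (49.2 to 51.6). A single scaffold, chrUn_NW_016683742v1, held 284 peaks at stage 56 and 245 at stage 61, which covered 193039 and 185610 bp within its first 494390 bp. This scaffold was singled out after its values were seen. The median peak area on scaffolds was 253 at stage 56 and 168 at stage 61, against 147 and 130 on chromosomes 1 to 10.

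A larger share of stage 56 sites was called at stage 61 than of stage 61 sites at stage 56. Of the 4564 stage 56 peaks, 3496 overlapped a stage 61 peak (76.6%, 75.3 to 77.8), against 20.9% after random placement. Of the 6806 stage 61 peaks, 3404 overlapped a stage 56 peak (50.01%, 48.8 to 51.2), against 13.3%. Overlapping peaks were about as many in both directions, so the greater length of the stage 61 list sets which share is larger. When the 4564 largest peaks of each list were compared, the shares were 65.5% and 62.4%, values that lists of equal length bring together by construction. On chromosomes 1 to 10, where chance overlap was small, the shares were 79.0% (77.0 to 80.8) against 0.253% and 42.1% (40.4 to 43.8) against 0.142%. Among isolated peaks the contrast was wider still. At stage 56, 448 of 506 (88.5%, 85.4 to 91.2) had a stage 61 partner, and at stage 61, 334 of 1286 (26.0%, 23.6 to 28.5) had a stage 56 partner, leaving 952 isolated stage 61 sites without one.

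Sharing rose with peak area. The tenth of stage 56 peaks with the smallest areas was shared in 54.0% of cases and the tenth with the largest in 97.6%, and for stage 61 the corresponding values were 19.8% and 91.6%. Stage 61 peaks without a partner had a median area of 81.0 and a median width of 303.5 bp, against 272.6 and 484 bp for those with one. Across the 3496 shared stage 56 peaks, the areas at both stages had a Spearman correlation of 0.59, which is across peaks and not across independent replicates. With list depth unknown, a stage 61 peak without a partner was not called at stage 56, which does not show that the site was closed there.

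**Figure D1:**
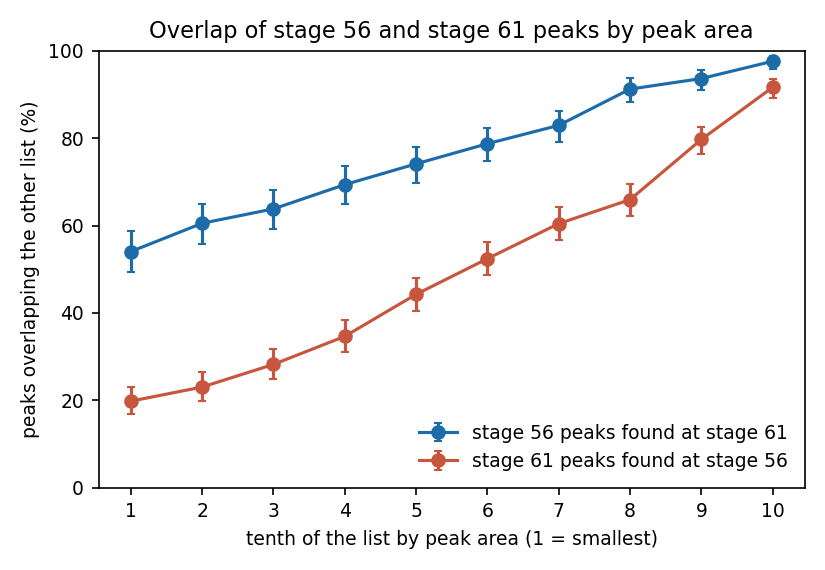
Share of peaks (%, vertical axis) that overlap a peak of the other stage by at least 1 bp, for 10 equal parts of each list ordered by peak area (horizontal axis, 1 is the smallest), with 1 library per stage; bars are exact 95% intervals that cover counting error only. The share climbs from 54.0% to 97.6% for stage 56 peaks and from 19.8% to 91.6% for stage 61 peaks. Area grows with peak width, and no random share was computed for each part.

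The same 2 regions led both lists. On chromosome 1, the peak at 47003165 to 47023647 had the largest area at stage 56 (40915) and overlapped the second-ranking stage 61 peak at 47008452 to 47016492 (14877). On chromosome 9, the peak at 45609130 to 45622681 ranked second at stage 56 (18358) and its partner at 45608933 to 45622717 ranked first at stage 61 (20349). The third-ranking stage 56 peak lay on scaffold chrUn_NW_016687091v1 at 347 to 4324 (12748), with a partner of rank 7 at stage 61. The third-ranking stage 61 peak lay on scaffold chrUn_NW_016684206v1 at 1173 to 9294 (13684), with a partner of rank 21 at stage 56. No gene annotation was used for these coordinates.

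A stretch of chromosome 8 from 97800001 to 98000000, chosen after its values were seen, departed from that pattern. It held 17 stage 56 peaks, of which 6 were shared, and 13 stage 61 peaks, of which 5 were shared. The strongest unshared stage 56 peaks of the whole list lay there, at 97951480 to 97953471 (area 4716, rank 59) and 97926721 to 97928521 (area 4226, rank 84). A stage 61 peak at 97878727 to 97880840 (area 3500, rank 79) had no stage 56 partner, but a stage 56 peak at 97878173 to 97878654 ended just before it. Likewise, the unshared stage 56 peak at 97912617 to 97913621 (rank 223) began just after the unshared stage 61 peak at 97911437 to 97912524. Some unshared peaks here thus lay beside a peak of the other stage without overlapping it. The stage 56 peaks of ranks 59 and 84 did not, since no stage 61 peak was called between 97912524 and 97970384.

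**Figure D2:**
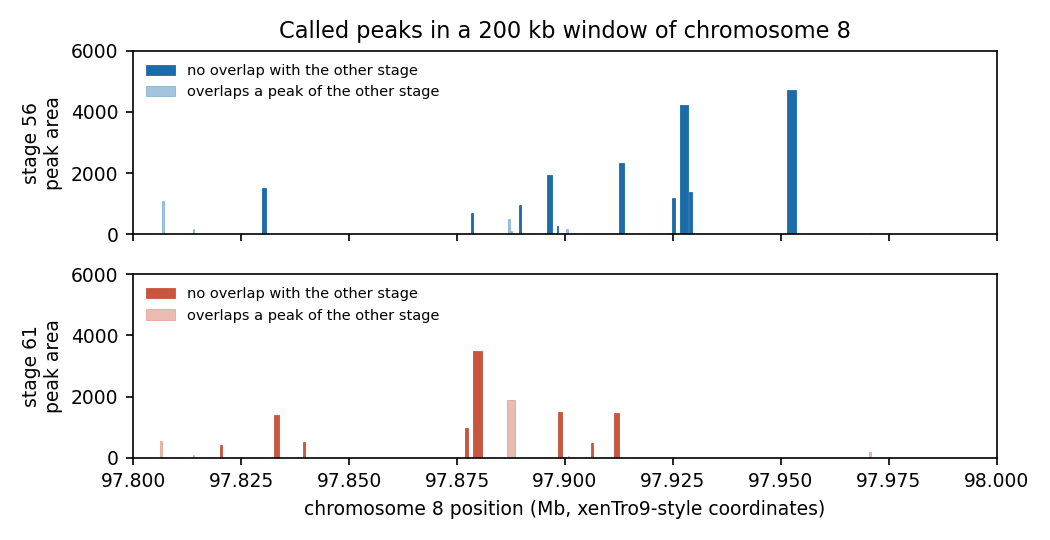
Called peaks of stage 56 (upper panel) and stage 61 (lower panel) along 200 kb of chromosome 8 (horizontal axis, Mb), where bar width is peak width and bar height is peak area (no unit), with 1 library per stage. Full colour marks the 11 stage 56 and 8 stage 61 peaks that overlap no peak of the other stage, and pale colour marks the shared ones.

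At stage 65 the question was which genes and gene groups carried accessible chromatin. Most skeletal, neural, muscle and signalling genes of the fixed lists had a peak at a gene end, but so did most genes: 18638 of 21748 protein-coding genes (85.7%, 85.2 to 86.2) had a peak within 1 kb of an end, against 70.7% when the peaks were placed at random. Both ends were occupied in 9818 genes. A gene said below to have no gene-end peak had none within 1 kb of an end. Peaks could still lie nearby: 95.2% of coding genes were occupied with 2.5 kb windows and 99.7% with gene bodies and 10 kb flanks. Genes without a gene-end peak differed in this, with 1 peak in the gene and flanks at grhl3 and 46 at pax7. Of 21 gene lists, 20 fell within the range of random lists, and epidermal genes were the exception, with fewer occupied members. Random lists of these sizes would put 0.456 of 21 lists below percentile 2.5 on average. Because most genes were occupied, the measure had little room upward: a fully occupied list would have passed percentile 97.5 for 3 of the 21 lists, so high occupancy of a list such as osteoclast or notochord genes does not set it apart. Folds quoted below come from the top of each list, up to 4 members per list. For comparison, the median best gene-end fold over all occupied coding genes was 4.34. By median fold, with unoccupied members set to 0, 2 lists lay below the range of random lists and 0 above it.

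Of all stage 65 peaks, 32541 overlapped a gene-end window (10.4%, 10.3 to 10.6), against a mean of 8.03% over random placements (range 7.92 to 8.14). The excess was largest for peaks with a fold of 4 to 6, of which 14.3% lay at gene ends, 1.69 times the random share. It was small below a fold of 3 (7.43%, ratio 1.07). Among the 800 peaks with a fold of 50 or more, 16.8% lay at gene ends, less than the 25.5% of random placements. By summit position, gene ends were 1.79 times as often occupied as flanks for folds of 4 to 8 and 0.347 times as often for folds of 8 and over. By overlap, peaks with folds of 8 to 15 and of 15 to 50 still lay at gene ends more often than random placements (15.7% against 12.3%, and 18.7% against 16.3%). For named genes with folds above 8, overlap and summit position thus give different pictures of the class their peaks belong to. At list members with such folds, peaks covered from 16.0% (tnfsf11) to 71.7% (gata1) of the gene and its 10 kb flanks. The median over all protein-coding genes was 17.9%. Coverage also varied among named members with folds under 8. It was 79.4% at coro1a, 68.6% at scx and 59.6% at thibz, but 9.03% at smad1 and 4.65% at nfatc1. A fold alone thus does not tell a focal peak from a widely covered stretch. Gene spans held 52.5% of all peaks against 51.3% at random, 48.5% against 55.3% for folds of 15 to 50, and 36.2% against 59.3% for folds of 50 and over.

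**Figure D3:**
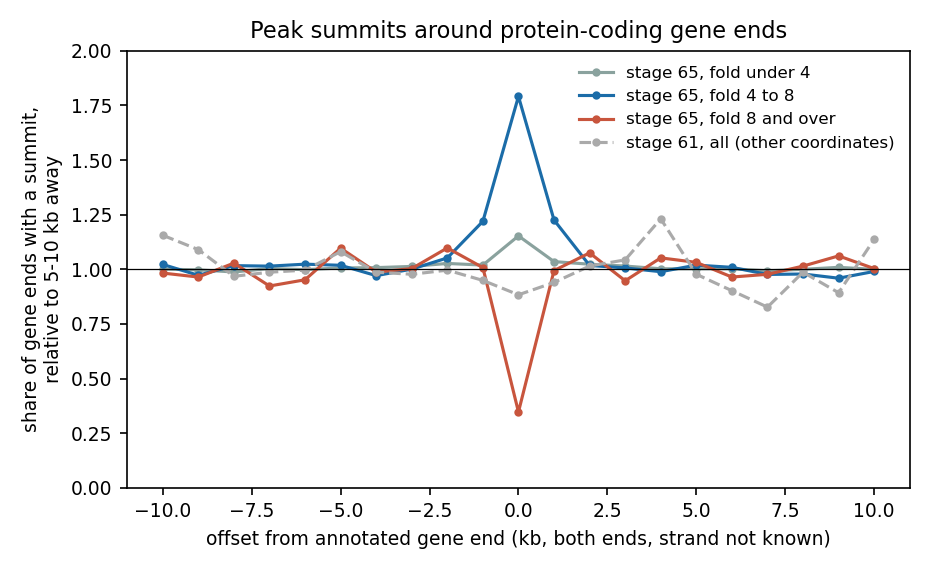
Share of protein-coding gene ends with a peak summit in 1 kb bins, relative to bins 5 to 10 kb away (vertical axis, ratio), against the offset from the gene end (horizontal axis, kb), for stage 65 peaks split by fold and for stage 61, whose coordinates are of another build; 1 library per stage. At offset 0 the ratio is 1.79 for folds of 4 to 8, 1.15 for folds under 4, 0.347 for folds of 8 and over, and 0.883 for stage 61.

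Cartilage genes had a peak at a gene end in 16 of 19 members, at percentile 33.3 of random lists. They included sox9, the master regulator of chondrocytes, with a fold of 20.7 at 30566170 to 30568459 on chromosome 10, its partners sox6 (16.6, chromosome 4, 2584867 to 2585910) and sox5 (7.79), and chad (10.9). No gene-end peak was called at acan, col9a1 or ucma, which encode cartilage matrix proteins. Hypertrophic cartilage genes had one in 10 of 11 members (percentile 61.1), led by the angiogenic factor vegfa (19.9, chromosome 5, 1676701 to 1678908), the mineralisation enzymes alpl (16.6) and phospho1 (12.0) and the hedgehog ligand ihh (5.54). The collagenase gene mmp13 had none. Bone genes had one in 13 of 15 members (percentile 47.9). The fold was 13.0 at bglap, which encodes osteocalcin, 5.84 at runx2, the osteoblast regulator (chromosome 5, 147507504 to 147508678), and 5.54 at both postn and dlx5, while phex had no gene-end peak.

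Osteoclast genes were occupied in 9 of 9 members (percentile 85.9). The fold was 18.7 at tnfsf11, which encodes the osteoclast-inducing ligand RANKL, 12.1 at mitf, 8.38 at dcstamp and 7.79 at nfatc1. Tendon and perichondrium genes were occupied in 8 of 10 members (percentile 27.7), with folds of 6.74 at scx, the tendon regulator, 5.84 at mkx, 5.24 at egr1 and 4.19 at prrx1, and none at gdf5 or tnmd. Notochord genes were occupied in 7 of 7 members (percentile 87.0), with folds of 4.94 at foxa1, 4.49 at foxa2, 4.19 at the BMP antagonist nog and 3.59 at foxj1. Somite and sclerotome genes were occupied in 14 of 16 members (percentile 66.1), including tbx6 (6.74), foxc2 and uncx (both 5.54) and foxc1 (5.24), and not cdx4.

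Skeletal muscle genes were occupied in 13 of 15 members (percentile 52.2), with folds of 22.2 at myod1, the muscle determination gene (chromosome 4, 903079 to 904290), 12.9 at mylpf, 5.69 at tnni2 and 4.94 at ryr1, and none at cacna1s or pax7. Spinal cord and neuron genes were occupied in 15 of 17 members (percentile 71.1), with folds of 14.8 at neurog1, 12.7 at elavl3 and 4.94 at both stmn2 and sox3, and none at elavl4. Erythroid genes were occupied in 7 of 8 members (percentile 55.7). Their peaks were strong at epor, the erythropoietin receptor gene (45.5, chromosome 3, 140143133 to 140147373), and at gata1, the erythroid regulator (43.0, chromosome 8, 1056715 to 1068049, 11335 bp wide), and weaker at slc4a1 (4.79) and alas2 (4.34), with none at hba1. With 10 kb flanks, peaks covered 66.4% of epor and 71.7% of gata1. Leukocyte genes were occupied in 9 of 9 members (percentile 85.1), with folds of 6.44 at coro1a, 4.49 at spi1, 4.19 at runx1 and 3.59 at csf1r.

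Epidermal genes stood lowest, with 3 of 7 members occupied against a random mean of 6.12 (percentile 0.335). Of the 11 fixed members 4, the keratin genes among them, matched no symbol and were not measured. The folds were 3.44 at cdh1, which encodes E-cadherin, 3.44 at grhl1 and 3.14 at epcam. No gene-end peak was called at tp63, the regulator of basal epidermis, or at grhl3, lamb3 or pkp1. With 7 measured members the interval of the share runs from 9.90% to 81.6%. With gene bodies and 10 kb flanks counted all 7 had a peak (percentile 50.3), as did 99.7% of all coding genes. That setting hardly separates lists. The list stayed below the range of random lists with 2.5 kb windows (percentile 0.08), for folds of 4 to 8 (0.895) and in the stronger 50% (1.835). It lay inside the range when peaks were assigned by summit (percentile 3.0). In the 4564 highest peaks 0 of 7 members were occupied, the lowest count possible, yet at percentile 36.8. That setting could not show a low list. Endothelial genes were occupied in 6 of 8 members (percentile 17.5), with folds of 13.5 at sox18, 4.49 at kdr, 3.89 at tie1 and 2.84 at pecam1 and none at erg or tek. The annotated sox18 span is long, with 97 peaks in it and its flanks at 2.59 per 10 kb. Which end of sox18 is the start is not known, so its peak may lie far from it. The endothelial median fold of 2.69 lay at percentile 1.94. By summit, 3 of 8 were occupied (percentile 1.05, outside the range of random lists).

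Thyroid hormone drives amphibian metamorphosis, and genes of its pathway were occupied in 15 of 16 members (percentile 77.7). The fold was 6.74 at the receptor partner gene rxra, 5.99 at both klf9 (chromosome 1, 129853066 to 129854716) and thibz (chromosome 3, 140193366 to 140195266), which are direct response genes, and 5.84 at dio3, which encodes the hormone-inactivating deiodinase. Only rxrg had none. Posterior hox genes, which pattern the rear of the axis, were occupied in 13 of 14 members (percentile 80.4), with folds of 5.54 at hoxd8, 5.39 at hoxa13, 4.64 at hoxc11 and 4.49 at hoxc12 and none at hoxa11. Anterior hox genes were occupied in 11 of 15 members (percentile 21.2), with folds of 10.6 at hoxb1, 10.5 at hoxb3 and 5.09 at hoxc5, and none at hoxa4, hoxb5, hoxd3 or hoxd4. In 2.5 kb windows all 15 anterior and all 14 posterior hox members were occupied, as were 95.2% of coding genes. The difference between the hox groups thus depended on the window and was not tested.

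BMP pathway genes were occupied in 14 of 14 members (percentile 94.2), with folds of 7.64 at bmp6 (chromosome 6, 89398092 to 89398861), 7.19 at smad6, 6.59 at bmpr1b and 5.99 at smad1. Hedgehog genes were occupied in 9 of 11 members (percentile 27.7), with folds of 10.9 at hhip, 8.23 at boc, 6.89 at dhh and 5.54 at gli3 and none at cdon or ptch1. Apoptosis and matrix breakdown genes were occupied in 12 of 14 members (percentile 41.1), with folds of 13.5 at timp3, 11.2 at casp9 and 6.74 at bcl2l1 and none at casp8 or ctsl. Cell cycle genes were occupied in 11 of 13 members (percentile 38.7), with folds of 14.4 at aurkb, 7.04 at plk1, 6.44 at mcm3 and 4.94 at mki67 and none at ccnb1 or mcm6. Housekeeping genes were occupied in 20 of 20 members (percentile 97.1), with folds of 9.43 at psmc3, 7.19 at hprt1, 6.59 at vcp and 5.99 at b2m.

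**Figure D4:**
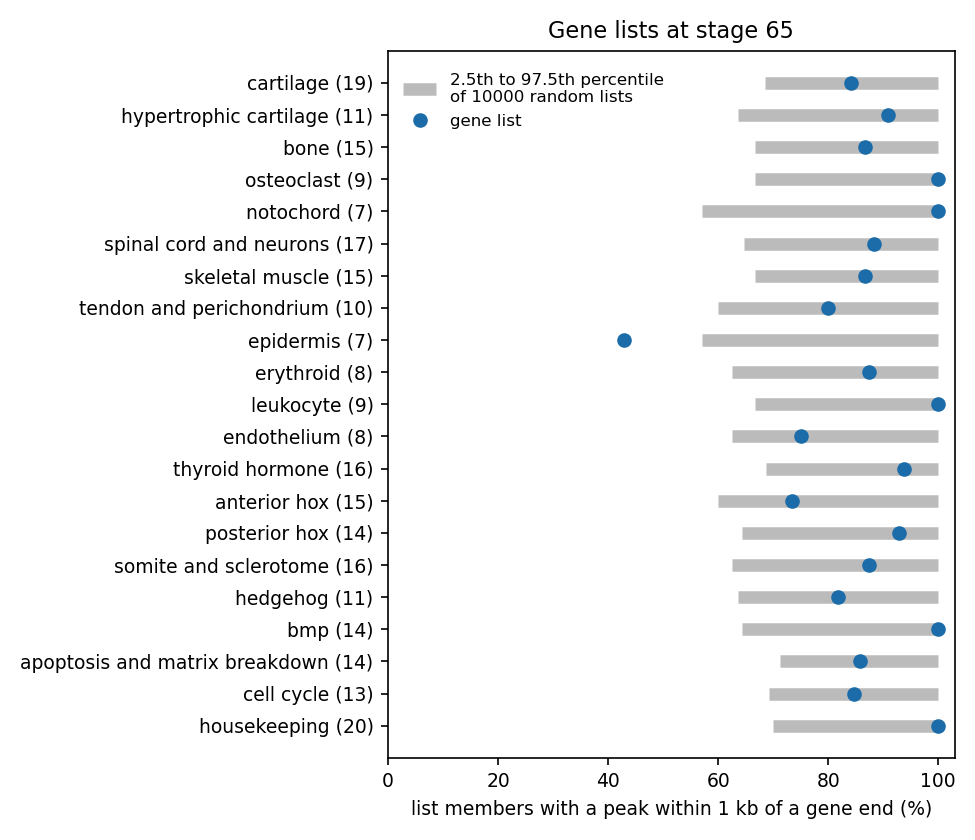
Share of the members of each gene list with a stage 65 peak within 1 kb of a gene end (points, %, 1 library), with the number of members found in the gene table in brackets; grey bars run from the 2.5th to the 97.5th percentile of 10000 random lists matched on gene length. Epidermal genes, at 42.9%, are the one list outside its bar.

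Among nuclear protein-coding genes with a gene symbol rather than a LOC number, the highest gene-end peaks at stage 65 belonged to tmem177 (fold 497, chromosome 9, 88007846 to 88010812), nyap1 (329.8, chromosome 3, 151458329 to 151467247), map2, which encodes a neuronal microtubule-binding protein (205, chromosome 9, 56018828 to 56019487), atp6v1al (181, chromosome 8, 147035774 to 147042702) and ddx18 (178, chromosome 9, 90922954 to 90930105). Of these the map2 peak was narrow, at 660 bp, and the other 4 were 2967 to 8919 bp wide. The highest peak of all lay on chromosome 5 at 433199 to 477679, had a fold of 4648 and spanned 161 annotated rRNA genes between LOC101731703, 10644 bp to its left, and mrpl2, 7793 bp to its right. The second lay on chromosome 2 at 180991085 to 180999694 (fold 2383) and overlapped no annotated gene. It lay 148594 bp to the right of zscan2, the last protein-coding gene of the chromosome. The third lay on chromosome 5 at 163984508 to 164001981 (fold 1725), 231 bp to the left of LOC108647387.

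Stage 65 also differed from the other stages in where its peaks lay and how large they were. Only 240 of its 311625 peaks (0.0770%) lay outside chromosomes 1 to 10, and 5 of its placed peaks were isolated. It had 1129 peaks wider than 10 kb, against 2 at stage 56 and 1 at stage 61. Its coordinate system and its kind of list differ from those of the other stages, so these differences cannot be assigned to the stage, and gene occupancy was not compared between stage 65 and the others.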

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

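The tests on the length of the stage 65 list, and the count of each tRNA peak once, were chosen after the results were seen. The other tests on tRNA genes were set before their results were seen.

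Peaks on the mitochondrial genome and on genes for structural RNAs lie outside the comparisons of protein-coding genes and stood far above background at stage 65. The mitochondrial genome was covered by 1 peak from 1 to 17610 with a fold of 566 (rank 22, pileup 3778), and the lists of stages 56 and 61 held 0 mitochondrial peaks. Of 463 rRNA genes, 457 lay under a peak (98.7%, 97.2 to 99.5), with a median fold of 449.9, against 70.5% of the same genes moved by 20 kb. The values were 525 of 614 for snRNA genes (85.5% against 43.5%, median fold 45.7) and 1621 of 2366 for tRNA genes (68.5% against 42.1%, median fold 14.5). These genes share few peaks: the 457 rRNA genes lay under 29, the 525 snRNA genes under 70 and the 1621 tRNA genes under 363. The rRNA interval counts genes as separate and is thus too narrow, and the median folds weigh each gene rather than each peak. The highest peak, over 161 rRNA genes, was 44481 bp wide. Genes moved by 20 kb can stay under such a peak, so the moved shares may run high.

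For the structural RNA genes, copies of a repeated gene adding up at one place would raise the fold of tRNA genes in arrays, and among tRNA genes under a peak those with at least 5 others within 10 kb had 3.68 times the median fold of those with none (2.27 to 7.78, resampling peaks). Counted once per peak the ratio was 1.07 (0.875 to 1.35), because 719 tRNA genes with a fold of 20 or more lay under only 35 peaks, so the array effect rests on few peaks and is not settled. Open chromatin at single small RNA genes would put lone tRNA genes under peaks more than 1.5 times as often as chance, and 26 of 82 lay there, 1.27 times the share after moving them (0.809 to 1.89). The bound set in advance, an interval that includes 1, was too loose to argue against this, since the interval also reaches above 1.5 with so few genes. Both explanations stay open, and no biological difference between stages was tested for them.

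The stage 65 list was 45.8 times as long as that of stage 61. Weak peaks admitted by a permissive threshold stay open: 75780 stage 65 peaks had a −log10 q of 10 or more, against 6806 stage 61 peaks in all, but the scales are unlike, since the largest −log10 q was 6.86 at stage 56, 5.90 at stage 61 and 102554 at stage 65, and the area floor near 20 of stages 56 and 61 has no counterpart at stage 65. Another build and another way of calling peaks cannot be told apart from the stage, since both changed together with it in a single library. Sequencing depth stays open as well, because it is unknown for stages 56 and 61, and a real difference in accessibility at stage 65 stays open, untested.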

How the results depend on the processing

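Alternatives restricted to folds of 4 to 8, to summits near gene ends and to isolated peaks were chosen after seeing the data. Merging peaks within 100 bp changed no count, because the closest peaks lay 101, 101 and 279 bp apart. On chromosomes 1 to 10 alone, stage 56 had 1836 peaks and stage 61 had 3376. Each alternative except equal numbers kept the stage 61 list longer, which favours a larger share for stage 56 in advance. The share of stage 56 peaks found at stage 61 stayed above the reverse share in every alternative. It was 75.3% in the stronger 50% of each list, 65.5% with equal numbers of peaks, 79.0% on chromosomes 1 to 10, 73.2% with 0.5 of the first peak covered, 59.5% with 0.5 of both covered and 88.5% for isolated peaks. The reverse share was 62.4% with equal numbers, 42.1% on chromosomes 1 to 10, 45.1% and 39.9% with the stricter overlaps and 26.0% for isolated peaks. Equal numbers bring the 2 directions together by construction.

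The gene-end share of stage 65 peaks was 13.1% in the stronger 50% (1.45 times random), 18.6% in the top 4564 (0.980 times random, so the excess ended there), 7.35% with 500 bp windows, 18.4% with 2.5 kb windows and 7.37% by summit. The cause of the lost excess was not tested. The share of coding genes with a peak was 67.5% in the stronger 50%, 4.29% in the top 4564, 95.2% with 2.5 kb windows, 99.7% with gene bodies and flanks, 42.02% for folds of 4 to 8 and 75.4% by summit; fewer peaks or wider windows set these by construction. The number of lists outside the range of random lists was 2 in the stronger 50%, where BMP genes stood high, 2 for folds of 4 to 8, where somite and sclerotome genes stood high, and 0 in the top 4564 and with gene bodies and flanks. In the top 4564 even 0 of 20 housekeeping genes lay at percentile 19.1, so no list could be called low. With gene bodies and flanks nearly all genes were occupied, so lists hardly differed. Epidermal genes were occupied in 0% of members in the top 4564, 0% for folds of 4 to 8 (percentile 0.895) and 100% with gene bodies and flanks. Their percentile was 0.08 with 2.5 kb windows and 1.835 in the stronger 50%. By summit their percentile was 3.0, inside the range, while endothelial genes fell to 1.05. Over the 21 lists, the share moved outside its interval in 2 lists in the stronger 50%, 7 with 2.5 kb windows, 16 with gene bodies, 18 for folds of 4 to 8 and 21 in the top 4564.

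Peak counts in the stronger 50% or in equal numbers are fixed by construction and were not run, nor were the motif alternatives, for which no genome sequence was used. No paired analysis was possible because each stage has 1 library. Read totals were not given in the sources used here, so how depth limits the lists was not measured; at stage 65 the median summit pileup was 21.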

Other observations

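The features described here were chosen after their values were seen. Other RNA gene classes at stage 65 lay closer to their background than rRNA, snRNA and tRNA genes did. Small nucleolar RNA genes lay under a peak in 155 of 342 cases (45.3%, 39.96 to 50.8), against 33.2% after moving them by 20 kb, with a median fold of 4.49. These 155 genes lay under 81 peaks, so the interval, which counts genes as separate, is too narrow. The shares were 27.3% against 23.5% for 187 miRNA genes, 74.4% against 73.9% for 2350 lncRNA genes and 66.1% against 55.0% for 548 pseudogenes. Protein-coding gene spans lay under a peak in 92.0% of cases against 90.4%.

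Endothelial and epidermal genes were outside the range of random lists in the number of peaks per length, but not in the length covered. Endothelial genes had a median of 1.43 peaks per 10 kb of gene and flanks (percentile 0.54 of random lists) and epidermal genes 1.42 (percentile 0.72), against a median of 2.45 over all protein-coding genes. The percentage of that length covered by peaks lay inside the range of random lists, at percentile 3.13 for endothelial and 15.8 for epidermal genes. No list lay above percentile 97.5 in density or in median fold, measures that are not capped by full occupancy. BMP genes had a median fold of 5.09 against a random mean of 4.08 (percentile 94.1).

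On chromosome 3, the window from 37600001 to 37700000 held 13 stage 56 peaks and 5 stage 61 peaks, and 0 of the 13 were shared. The strongest of the 13 had an area of 1846 (rank 309). Among 45 windows of 100 kb with at least 8 stage 56 peaks, the median shared percentage was 75, and after this window the next lowest, at 25%, lay in the chromosome 8 stretch described above. Of the 11 unshared stage 56 peaks among the 456 largest, 5 lay in that chromosome 8 stretch.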
